A study of Homo sapiens with 24 samples.

How the data were processed

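RNA was measured in 24 samples of MOLM14 and OCI-AML2 cells after 24 h with DMSO, AZ2 or ARM165, in 6 groups of 4 libraries. Per the labels' protocols, total RNA was purified on columns and poly(A) mRNA libraries were made with a stranded TruSeq kit and sequenced on a NovaSeq instrument (the instrument is named in the series description). Per the submitters' processing notes, transcripts were quantified with kallisto (version not stated). The genome build, annotation, the summing to genes and the method of scaling were not given in the sources used here. Doses, culture dates and the origin of replicates were not given either, and the labels do not say which compound is the degrader named in the series title.

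The deposited signal values are normalized estimated counts per gene symbol, in 1 table for each cell line with 35587 symbols and 12 libraries. Their values have fractions and differ in total between libraries, as 1 factor per library would leave them, and the tables were scaled separately, so no level was compared between lines. Of the values above 0, 15.1 to 15.9% lay within 0.01 of a whole number after division by the value of 1 read in that library, so whole counts could not be recovered and tests that need whole counts were not run. Estimated reads per library, from that value of 1 read, ranged from 35.4 M to 59.0 M. The group means were 50.0 M, 37.9 M and 41.1 M for DMSO, AZ2 and ARM165 in MOLM14, and 40.1 M, 47.6 M and 45.0 M in OCI-AML2. At this depth 18889 to 19699 symbols had a value above 0, and the median standard error of a log2 change was 0.099 in MOLM14, 0.12 in OCI-AML2 and 0.15 for a difference between the lines. Of the symbols, 35403 (99.5%) are in GENCODE release 29 and 7193 have clone-style names, and the tables hold no coordinates.

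Samples were grouped by line and treatment from their labels before the files were opened, and 0 columns were left out. Values were taken as log2(value + 1), and genes with at least 10 in at least 4 libraries of a line were kept. Per line, a linear model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 (with statmod 1.5.0 in R 4.3.3), with a variance trend and empirical Bayes moderation (9 residual degrees of freedom, 5.63 prior ones in MOLM14 and 5.67 in OCI-AML2). AZ2 and ARM165 were each compared with DMSO and with each other. The difference of each change between the lines was tested in 1 fit of 24 libraries over 14287 genes kept in both lines (18 residual and 5.32 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Intervals are 95% intervals of single genes without adjustment. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

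The 27 gene lists were fixed before the files were opened: PI3K and AKT components, FOXO-induced genes, ERK pathway feedback genes, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, sterol biosynthesis, fatty acid synthesis, ATF4 and amino acid stress genes, glycolysis, nuclear oxidative phosphorylation subunits, mitochondrially encoded mRNAs, DNA replication, mitosis, p53 target genes, BCL2 family, monocyte and granulocyte differentiation, leukaemia stem and progenitor genes, NF-kB and inflammatory cytokines, interferon-stimulated genes, lysosome and autophagy genes, heat shock and ER chaperones, major histocompatibility complex genes, replication-dependent histone mRNAs, and markers of T and NK cells, B cells, erythroid cells and megakaryocytes, and epithelial cells and fibroblasts. Lists with at least 5 kept members were tested against the other genes with camera in limma at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They were also tested with fry, which asks whether a list shifted in a common direction and not whether it differs from other genes. The estimated correlation makes the camera test stricter, and some of its p-values are given as a range over lists. Members were also counted with p-values adjusted over the list alone.

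The rule for named genes was written before any values were seen. It took PIK3CG, PIK3R5, PIK3R6, AKT1 and AKT2 always, then up to 8 of the largest called rises and falls. Within a line these needed a group mean of at least 50 and no overlap between the 2 groups of 4 libraries. For differences between lines neither condition applied. From each list the rule took up to 4 called members with the smallest adjusted p, or up to 2 of the highest mean where no member was called. After a first run had been seen, this was narrowed in the rule's own order to the first 3 rises and falls for ARM165 against DMSO and for its difference between lines, 2 for ARM165 against AZ2, 2 members per list and 1 per marker list, with FDPS, MT-CO1 and MT-CO3 alone kept for AZ2 in MOLM14, leaving out sex-linked, pseudogene, multicopy and read-through names. CYP51A1, IDI1, FDPS and AC025048.6 in OCI-AML2 and FTL were named outside the rule, after their values were seen. Some genes that the rule or a list takes are not reported here.

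The tests were run on simulated data with known changes in 50 genes per fold. The changed genes were drawn from those with a DMSO mean of at least 50. Each gene was given the typical spread at its level, so the rates do not hold for low or more variable genes. For genes, changes were put only into ARM165 libraries, so recovery was not measured for AZ2 against DMSO. How strict the adjusted cut is depends on how many genes change. Far more genes changed with ARM165 in the real data and fewer with AZ2, so the rates are the sensitivity of neither comparison. For ARM165 against DMSO, changes of 1.3, 1.5, 2 and 4 times were recovered for 76, 92, 98 and 100% of genes in MOLM14, for 68, 82, 94 and 100% in OCI-AML2, and for 46, 68.75, 90 and 94% between the lines (48 genes at 1.5 times). Between 0 and 13 unchanged genes were called per comparison. A list of 30 genes raised 1.3 times was called, and 0 of 25 random lists were. Genes were simulated independently of each other, so this could not test false calls of lists whose members vary together. The correlation of AZ2 and ARM165 changes was set against 100 simulations of unchanged groups that share controls. In 40 such simulations of the calls no gene was called with both compounds, since almost none is called without a change, so they give no reference for the overlap. A form of the simulation with the variance of the DMSO libraries was added after the first value was seen, and both are given.

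The alternatives, fixed before any values were seen, were log2(value + 0.5) and log2(value + 5), no filter, a minimum value of 50, upper quartile rescaling, quantile normalization, the replicate number as a block, only the groups compared, robust empirical Bayes, library weights, each library left out, and the other list tests. Count models were planned and not run, because whole counts could not be recovered. The library groups were also split into all 35 pairs of 4 and 4 within a line, and into 100 drawn splits for differences between lines.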

Results

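Gene expression was measured by RNA sequencing in MOLM14 and OCI-AML2, established cell lines derived from patients with acute myeloid leukaemia, after 24 h with the DMSO vehicle or with AZ2 or ARM165, compounds known in the labels only by these codes. The 24 libraries formed 6 groups of 4 (line by treatment). Estimated reads per library ranged from 35.4 M to 59.0 M, and 18889 to 19699 of 35587 gene symbols had a value above 0. Values are normalized estimated reads. Libraries of a line were scaled to each other, so a rise or fall is relative to the other genes. A change in total RNA per cell cannot be read from these values. Each line was scaled on its own, so levels were never compared across lines. The labels state neither the doses nor whether replicates were separate cultures. P-values therefore measure the spread between these libraries, which may be technical, and the compounds were compared at doses not known to match. Group levels are means ± SD (n = 4). Changes are log2 fold changes ± SE on the log2(value + 1) scale, which understates the change of genes with low values. Adjusted p-values are from limma over all genes tested, or from its camera test for gene lists.

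The series title concerns PI3K gamma and AKT signalling in acute myeloid leukaemia. The first question was how AZ2 altered gene expression in each line. In MOLM14, no gene passed the test after AZ2. PIK3CG, which encodes the catalytic subunit of PI3K gamma, was at 3161 ± 201 with DMSO and 2957 ± 278 with AZ2 (change -0.099 ± 0.067, 95% interval -0.24 to 0.045, adjusted p = 0.917). The regulatory subunit genes PIK3R5 and PIK3R6 had intervals of -0.23 to 0.18 and -0.69 to -0.0033. The kinase genes AKT1 and AKT2 had intervals of -0.14 to 0.13 and -0.065 to 0.14. Adjusted p for these 4 genes ran from 0.839 to 0.996. By limma, 0 of 15288 genes changed, while 899 (5.88%) had an unadjusted p under 0.05, and the median SE was 0.099. A fit with only the DMSO and AZ2 libraries called 1 gene, lower with AZ2. The count was 3, all lower, without AZ2 replicate 3 and 1 without DMSO replicate 4, AZ2 replicate 1 or ARM165 replicate 4.

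Of 26 gene lists tested for AZ2 in MOLM14, 6 were called with the preset correlation of camera and 0 with an estimated correlation. Mitochondrially encoded mRNAs had the highest median of these, at 0.15 (adjusted p = 8.45e-12, adjusted p = 0.369 with an estimated correlation). In this list 0 of 13 members passed over all genes, and 7 were higher when adjusted over the list alone. The changes were 0.14 ± 0.052 for MT-CO1 and 0.17 ± 0.048 for MT-CO3, genes of cytochrome c oxidase, and neither passed over all genes (adjusted p = 0.732 and 0.599). For the sterol biosynthesis list the median was -0.073 (adjusted p = 0.000581, adjusted p = 0.578 with an estimated correlation). Of its 24 measured members, 19 had a change below 0 and 4 an interval below 0, with changes from -0.23 to 0.069. Among its most abundant members, FDPS had a change of 0.013 ± 0.055. The p53 target list had a median of -0.073 (adjusted p = 0.000202, adjusted p = 0.423 with an estimated correlation) and 5 members lower when adjusted over the list alone. Nuclear oxidative phosphorylation genes had a median of 0.044 (adjusted p = 0.000202, adjusted p = 0.919 with an estimated correlation). The median was -0.13 for the NF-kB and cytokine list (adjusted p = 0.0203, adjusted p = 0.369 with an estimated correlation). It was 0.063 for the cytosolic ribosomal proteins (adjusted p = 1.60e-05, adjusted p = 0.919 with an estimated correlation). With quantile normalization the ribosomal and NF-kB calls were lost (adjusted p = 0.910 and 0.0587). For fatty acid synthesis the median was -0.078 (adjusted p = 0.0525, but 0.0236 with quantile normalization). The other 20 lists had adjusted p from 0.0525 to 0.968, and for 4 of them the median, mean and test differed in sign. Among markers of other cell types, the epithelial and fibroblast list had 1 member lower when adjusted over the list alone (list adjusted p = 0.783).

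In OCI-AML2, a small set of genes fell with AZ2, most of them genes of sterol and fatty acid synthesis. HMGCS1, an early enzyme of the mevalonate pathway, fell from 1294 ± 99.2 to 728 ± 70.6 (change -0.83 ± 0.087, adjusted p = 0.000593). The fatty acid desaturase gene FADS2 fell from 1607 ± 64.6 to 923 ± 48.5 (change -0.80 ± 0.080, adjusted p = 0.000453). Each was lower in 4 of 4 AZ2 libraries than in every DMSO library, as the rule for naming the largest falls required. EGR1, an immediate early gene of the ERK pathway, was the only gene called higher with the main settings, from 1547 ± 63.3 to 2221 ± 154 (change 0.52 ± 0.066, adjusted p = 0.00335). Several alternatives, such as quantile normalization, called 2 genes higher, and the one with no filter called 5. PIK3CG was at 3084 ± 199 with DMSO and 3048 ± 95.6 with AZ2 (interval -0.14 to 0.11). PIK3R5, PIK3R6, AKT1 and AKT2 had intervals of -0.057 to 0.24, -1.07 to 0.31, -0.084 to 0.18 and -0.19 to 0.16. All 5 genes had an adjusted p of at least 0.996.

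Of the 24 measured sterol biosynthesis genes, 10 fell with AZ2 in OCI-AML2 over all genes and 23 when adjusted over the list alone. Besides HMGCS1, those that fell over all genes included changes of -0.64 ± 0.063 for INSIG1, -0.63 ± 0.089 for MSMO1, -0.62 ± 0.10 for MVK, -0.55 ± 0.068 for ACAT2, -0.54 ± 0.090 for CYP51A1, -0.50 ± 0.062 for FDFT1, -0.49 ± 0.070 for IDI1 and -0.33 ± 0.058 for FDPS. CYP51A1, IDI1 and FDPS lie outside the rule for named genes and were named after their values were seen. All 24 sterol genes had a change below 0, from -0.83 to -0.089, and the median was -0.44 (adjusted p = 4.65e-55, adjusted p = 6.16e-05 with an estimated correlation). In the fatty acid synthesis list, 3 of 14 measured members fell, 0 rose and 11 did not pass, with 4 lower when adjusted over the list alone. The median was -0.14 (adjusted p = 9.59e-08, adjusted p = 0.00206 with an estimated correlation). Besides FADS2, SCD, the stearoyl-CoA desaturase gene, fell by 0.43 (SE 0.055) and FADS1 fell by 0.42 (SE 0.073) on the log2 scale.

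**Figure D1:**
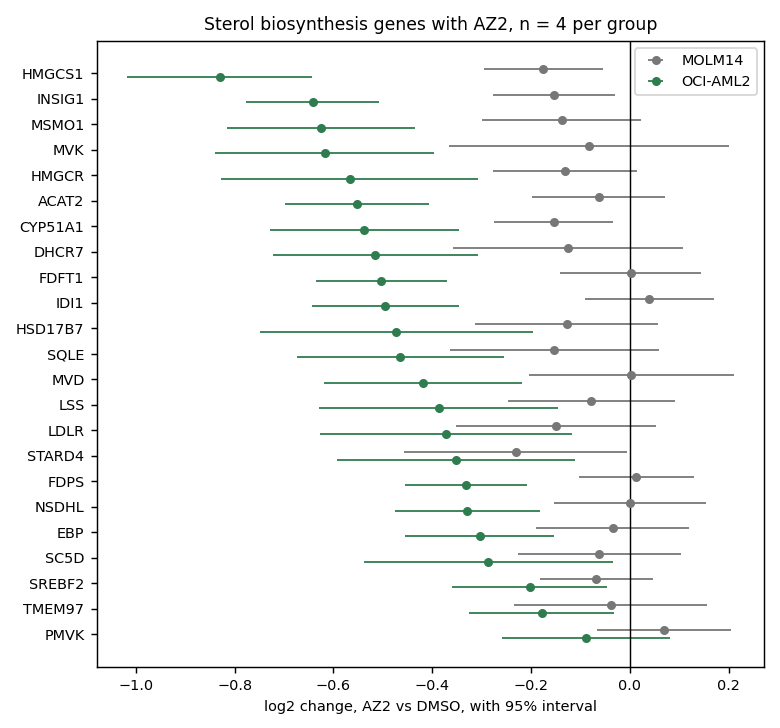
Log2 change of 23 of the 24 measured sterol biosynthesis genes with AZ2 against DMSO (horizontal axis, log2 scale; bars are 95% intervals from limma; n = 4 libraries per group), MOLM14 in grey and OCI-AML2 in green. The interval lay below 0 for 22 of 23 genes in OCI-AML2 and for 4 of 23 in MOLM14.

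Over all 15377 genes tested in OCI-AML2, 17 changed with AZ2 by limma, 1 higher and 16 lower. Of these, 0 of the higher and 3 of the lower ones had a log2 change of at least 1 in size. Outside the sterol and lipid genes, C6orf223 fell by 1.21 (SE 0.19) and CECR2 fell by 1.07 (SE 0.18) on the log2 scale. The last, AC025048.6, known only by a clone name, averaged 62.99 with DMSO and 0.484 with AZ2 and was also named after its value was seen. Its change of -5.23 ± 0.87 depends on the 1 added to each value, and with 5 added it was -3.34 and the call was lost (adjusted p = 0.101). The ERK feedback list, with 1 of 19 members called (EGR1), had a median of 0.039 (adjusted p = 0.000965, adjusted p = 0.165 with an estimated correlation). Small shifts were also called with the preset correlation for nuclear oxidative phosphorylation genes (median -0.062, adjusted p = 0.000864, adjusted p = 0.862 with an estimated correlation) and for heat shock and ER chaperones (median -0.061, adjusted p = 0.000938, adjusted p = 0.701 with an estimated correlation). Another call with the preset correlation, for mitochondrially encoded mRNAs (median 0.087, adjusted p = 0.000534, adjusted p = 0.831 with an estimated correlation), was also lost with quantile normalization (adjusted p = 0.0812). The other 18 lists had adjusted p from 0.0734 to 0.991, and for 6 of them the median, mean and test differed in sign. Only 1 member each of the ATF4 list and the monocyte list was lower when adjusted over the list alone. The number of changed genes was 9 without DMSO replicate 1 or AZ2 replicate 2, 10 without DMSO replicate 4 or AZ2 replicate 3, and 11 without AZ2 replicate 1. With no filter, 5 genes were higher and 10 lower. With the replicate number as a block, 10 genes changed, 9 of them lower. The calls of FADS1, MVK, C6orf223 and CECR2 were lost in 11, 8, 6 and 7 of 12 fits that each left out 1 library. Adjusted p reached 0.202, 0.146, 0.111 and 0.112. Those of CYP51A1, FDPS and AC025048.6 were lost in 8, 9 and 6 of 12, with adjusted p up to 0.127, 0.157 and 0.140.

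The next question was whether the lines responded to AZ2 differently. The fall of sterol genes was larger in OCI-AML2. Differences between the lines were -0.66 ± 0.10 for HMGCS1, -0.53 ± 0.094 for IDI1, -0.50 ± 0.092 for FDFT1 and -0.49 ± 0.085 for INSIG1 (OCI-AML2 minus MOLM14, adjusted p = 0.0174, 0.0388, 0.0480 and 0.0388). They were the only genes called of 14287 tested by limma (746, or 5.22%, at an unadjusted p under 0.05). Of 24 sterol genes, 4 were lower over all genes and 16 when adjusted over the list alone. The median difference was -0.35 (adjusted p = 1.38e-29, adjusted p = 0.000120 with an estimated correlation). For the PI3K gamma and AKT genes the differences were 0.084 ± 0.088 for PIK3CG, 0.11 ± 0.11 for PIK3R5, -0.034 ± 0.37 for PIK3R6, 0.051 ± 0.089 for AKT1 and -0.052 ± 0.093 for AKT2, none passing (adjusted p of at least 0.966). With the preset correlation 10 other lists were called, with medians between -0.10 and 0.050. Each of these calls was lost, with adjusted p from 0.213 for fatty acid synthesis to 0.813 for the ribosomal proteins with an estimated correlation, and the sign of the test of the ribosomal list reversed with quantile normalization (adjusted p = 0.566). The gene count of 4 was unstable. It was 0 without MOLM14 DMSO replicate 1, 2 or 4, MOLM14 AZ2 replicate 3, OCI-AML2 DMSO replicate 1 or OCI-AML2 AZ2 replicate 1 or 3, and 7 without MOLM14 DMSO replicate 3. The adjusted p of HMGCS1 ranged up to 0.0772 and that of FDFT1 up to 0.186 over the alternatives. IDI1 and INSIG1 each lost the call in 14 of 34 alternatives (adjusted p up to 0.154), among them the replicate block.

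ARM165 was then compared with DMSO in MOLM14. PIK3CG fell from 3161 ± 201 to 2200.5 ± 109.8 (change -0.52 ± 0.067, adjusted p = 4.63e-06). PIK3R6 fell from 213 ± 34.99 to 136 ± 19.9 (change -0.64 ± 0.16, adjusted p = 0.00229). PIK3R5 rose from 306 ± 28.8 to 1073 ± 56.6 (change 1.81 ± 0.096, adjusted p = 1.49e-10). AKT1 fell from 5706 ± 285 to 2725 ± 241 and AKT2 from 2797 ± 110.3 to 1419 ± 64.4 (changes -1.07 ± 0.063 and -0.98 ± 0.048, adjusted p = 4.96e-10 and 6.07e-11). Each of these 5 genes was on its side of the DMSO mean in 4 of 4 ARM165 libraries. In the PI3K and AKT component list as a whole, 13 of 26 measured members rose, 10 fell and 3 did not pass (adjusted p = 0.612). PIK3CD, which encodes the catalytic subunit of PI3K delta, fell by 1.42 (SE 0.054) on the log2 scale.

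**Figure D2:**
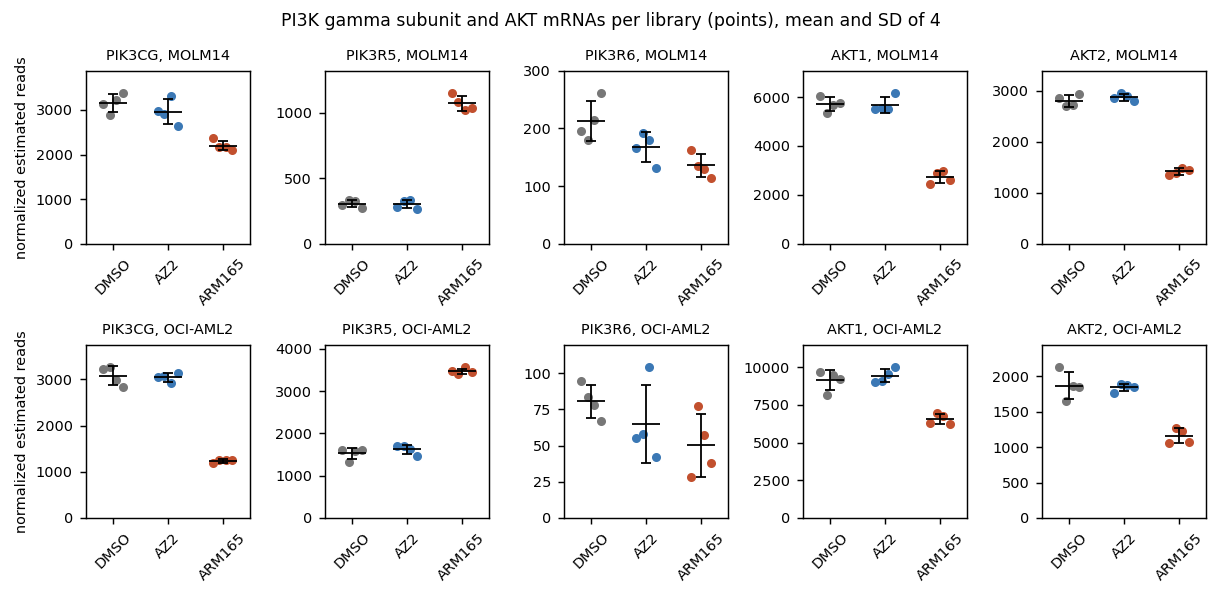
Normalized estimated reads (vertical axis, from 0) of PIK3CG, PIK3R5, PIK3R6, AKT1 and AKT2 in each library with DMSO, AZ2 or ARM165 (horizontal axis), with the mean and SD of 4 libraries, for both lines; each line was scaled on its own. PIK3R5 averaged 1073 with ARM165 against 306 with DMSO in MOLM14 and 3472 against 1526 in OCI-AML2.

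Beyond these genes, 10623 of 15288 genes (69.5%) changed with ARM165 in MOLM14 by limma, 5427 higher and 5196 lower, of which 2256 and 1798 had a log2 change of at least 1 in size. The median size of the log2 change over all genes tested was 0.63. That is larger than the change of PIK3CG, near that of PIK3R6 and smaller than those of PIK3R5, AKT1 and AKT2. Among the genes with the largest rises, SPRR2D, a small proline-rich protein gene of the epidermis, was listed at 0 in every DMSO library and at 921, 971, 1054 and 1076 with ARM165. HEY1, a transcriptional repressor downstream of Notch, was at 0, 1.44, 0 and 0 with DMSO and 519, 469.8, 483 and 549 with ARM165. KLHDC7B was at 3.94, 0, 5.53 and 1.04 with DMSO and 1119, 1227, 1039 and 988 with ARM165. Among the largest falls were S100A8 (-4.08 ± 0.14), APLN (-3.81 ± 0.33) and ANXA8 (-3.69 ± 0.13). S100A8 encodes a calcium-binding protein of myeloid cells and APLN the peptide apelin. SPRR2D and ANXA8 have close paralogs, so their shares of reads are uncertain.

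Most members of the DNA replication, mitosis, MYC target and ribosomal protein lists fell in MOLM14. In the DNA replication list, 40 of 40 measured members fell, with a median of -1.39 (adjusted p = 3.23e-17, adjusted p = 0.104 with an estimated correlation). Examples were UHRF1 (-2.13 ± 0.052) and FEN1 (-1.97 ± 0.055). Likewise, 34 of 34 measured members fell in the mitosis list (median -1.26, adjusted p = 2.05e-15, adjusted p = 0.132 with an estimated correlation). Examples were TPX2 (-1.31 ± 0.043) and KIF11 (-1.33 ± 0.044). In the list of MYC targets and ribosome biogenesis, 33 of 33 measured members fell (median -1.40, adjusted p = 5.36e-16, adjusted p = 0.104 with an estimated correlation). Examples were NOP56 (-1.61 ± 0.042) and NOLC1 (-1.45 ± 0.042). In the cytosolic ribosomal protein and elongation factor list, 31 of 36 measured members fell, 0 rose and 5 did not pass (median -0.30, adjusted p = 1.36e-05, adjusted p = 0.538 with an estimated correlation), but with quantile normalization the sign of the list test reversed (adjusted p = 0.692). The elongation factor gene EEF1A1 fell by 1.56 (SE 0.078) and RPL3 fell by 0.86 (SE 0.054) on the log2 scale. Both have processed pseudogenes that can share reads.

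Lipid and energy metabolism genes mostly fell. For sterol biosynthesis, 22 of 24 measured members fell, 0 rose and 2 did not pass (median -1.16, adjusted p = 1.50e-09, adjusted p = 0.104 with an estimated correlation). TMEM97, a member, fell by 2.54 (SE 0.092) on the log2 scale. For fatty acid synthesis, 8 of 14 measured members fell, 2 rose and 4 did not pass (adjusted p = 0.00908, adjusted p = 0.132 with an estimated correlation). SCD fell by 1.63 (SE 0.049) and ME1, the cytosolic malic enzyme gene, rose by 1.78 (SE 0.060) on the log2 scale. In nuclear oxidative phosphorylation, 38 of 44 measured members fell, 1 rose and 5 did not pass (median -0.53, adjusted p = 5.73e-09, adjusted p = 0.411 with an estimated correlation). Examples were ATP5MC1 (-1.81 ± 0.071) and NDUFS7 (-1.31 ± 0.065). Of the mitochondrially encoded mRNAs, 11 of 13 measured members fell, 1 rose and 1 did not pass (adjusted p = 0.00326, adjusted p = 0.495 with an estimated correlation). The call was lost with quantile normalization (adjusted p = 0.4998). Examples were MT-ND5 (-0.67 ± 0.052) and MT-ND6 (-0.63 ± 0.059). The glycolysis list moved both ways: 16 of 24 measured members fell, 8 rose and 0 did not pass (adjusted p = 0.00819, adjusted p = 0.513 with an estimated correlation). In it LDHA, the lactate dehydrogenase A gene, fell by 1.80 (SE 0.060) and VEGFA, an angiogenic growth factor gene rather than a glycolytic one, rose by 2.24 (SE 0.055) on the log2 scale.

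Most members of the p53 target, ATF4, FOXO, NF-kB, lysosome and histone lists rose. In the p53 target list, 23 of 24 measured members rose, 1 fell and 0 did not pass (median 1.52, adjusted p = 1.50e-09, adjusted p = 0.104 with an estimated correlation). Examples were TP53INP1 (2.93 ± 0.064), BBC3 (2.82 ± 0.075) and CDKN1A (2.70 ± 0.051). CDKN1A encodes the cell cycle inhibitor p21 and BBC3 a pro-apoptotic BCL2 family protein. For ATF4 and amino acid stress, 25 of 33 measured members rose, 2 fell and 6 did not pass (median 0.93, adjusted p = 5.28e-09, adjusted p = 0.174 with an estimated correlation). Examples were DDIT3 (3.91 ± 0.059) and SESN2 (2.72 ± 0.047). For FOXO-induced genes, 18 of 28 measured members rose, 6 fell and 4 did not pass (median 0.72, adjusted p = 0.00727, adjusted p = 0.278 with an estimated correlation). Examples were TXNIP (2.19 ± 0.047) and FOXO3 (1.66 ± 0.046). In the NF-kB and cytokine list, 20 of 25 measured members rose, 2 fell and 3 did not pass (median 1.31, adjusted p = 0.000107, adjusted p = 0.0905 with an estimated correlation). Examples were IL1B (3.94 ± 0.16) and IRF1 (1.90 ± 0.050). In the lysosome and autophagy list, 23 of 38 measured members rose, 10 fell and 5 did not pass (median 0.51, adjusted p = 0.00324, adjusted p = 0.276 with an estimated correlation). Examples were PSAP (2.59 ± 0.046) and SQSTM1 (2.27 ± 0.041). Of the replication-dependent histone genes, 14 of 14 measured members rose (median 2.81, adjusted p = 0.000398, adjusted p = 0.104 with an estimated correlation). Examples were HIST1H2AC (4.66 ± 0.18) and HIST1H1C (4.75 ± 0.19). Histone genes are a family of near-identical copies, so single members are uncertain.

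Other lists moved both ways in MOLM14 and were not called. In ERK feedback, 8 of 19 measured members rose, 7 fell and 4 did not pass (median -0.073, mean 0.33, adjusted p = 0.661). PHLDA1 rose by 5.12 (SE 0.072), and MYC, a transcription factor gene rather than a feedback regulator, had a change of -1.70 ± 0.070. In the BCL2 family, 8 of 15 measured members rose, 5 fell and 2 did not pass (adjusted p = 0.374). The pro-apoptotic gene BMF rose by 3.81 (SE 0.13). For monocyte and granulocyte differentiation, 14 of 32 measured members fell, 13 rose and 5 did not pass (adjusted p = 0.252). Members included LYZ (-2.93 ± 0.049) and IRF8 (-1.48 ± 0.046), which encode lysozyme and a myeloid transcription factor. For leukaemia stem and progenitor genes, 12 of 24 measured members rose, 11 fell and 1 did not pass (adjusted p = 0.615). Members included PRTN3 (-2.53 ± 0.091) and FLT3 (-1.18 ± 0.046). Among interferon-stimulated genes, 12 of 31 measured members rose, 9 fell and 10 did not pass (adjusted p = 0.416). Members included BST2 (-2.06 ± 0.078) and STAT2 (1.84 ± 0.099). Among heat shock and ER chaperones, 14 of 24 measured members fell, 9 rose and 1 did not pass (adjusted p = 0.177). Members included HSPA8 (-2.77 ± 0.067) and HSPH1 (-1.63 ± 0.043). Among the major histocompatibility complex genes, 9 of 17 measured members fell, 5 rose and 3 did not pass (adjusted p = 0.177). Members included TAP2 (-1.79 ± 0.077) and CD74 (-1.38 ± 0.068).

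Markers of other cell types were few in MOLM14. Of the T and NK cell markers, 4 of 5 measured members fell, 1 rose and 0 did not pass (adjusted p = 0.549). CD8A rose by 5.19 (SE 0.32). Of the B cell markers, 3 of 6 measured members fell, 1 rose and 2 did not pass (adjusted p = 0.661). FCRLA rose by 5.06 (SE 0.19). Of the epithelial and fibroblast markers, 2 of 5 measured members rose, 0 fell and 3 did not pass (adjusted p = 0.291). KRT18 rose by 0.73 (SE 0.063). Only 2 erythroid and megakaryocyte markers were measured, too few to test, and GP9 had a change of -0.93 ± 0.35 (adjusted p = 0.0286, up to 0.0908 in fits without 1 library). In all, 15 of 26 lists were called with the preset correlation and 0 with an estimated one. Counts adjusted over the list alone equalled those over all genes except for the ribosomal proteins (32 lower), fatty acid synthesis (9 lower) and leukaemia stem and progenitor genes (12 lower).

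**Figure D3:**
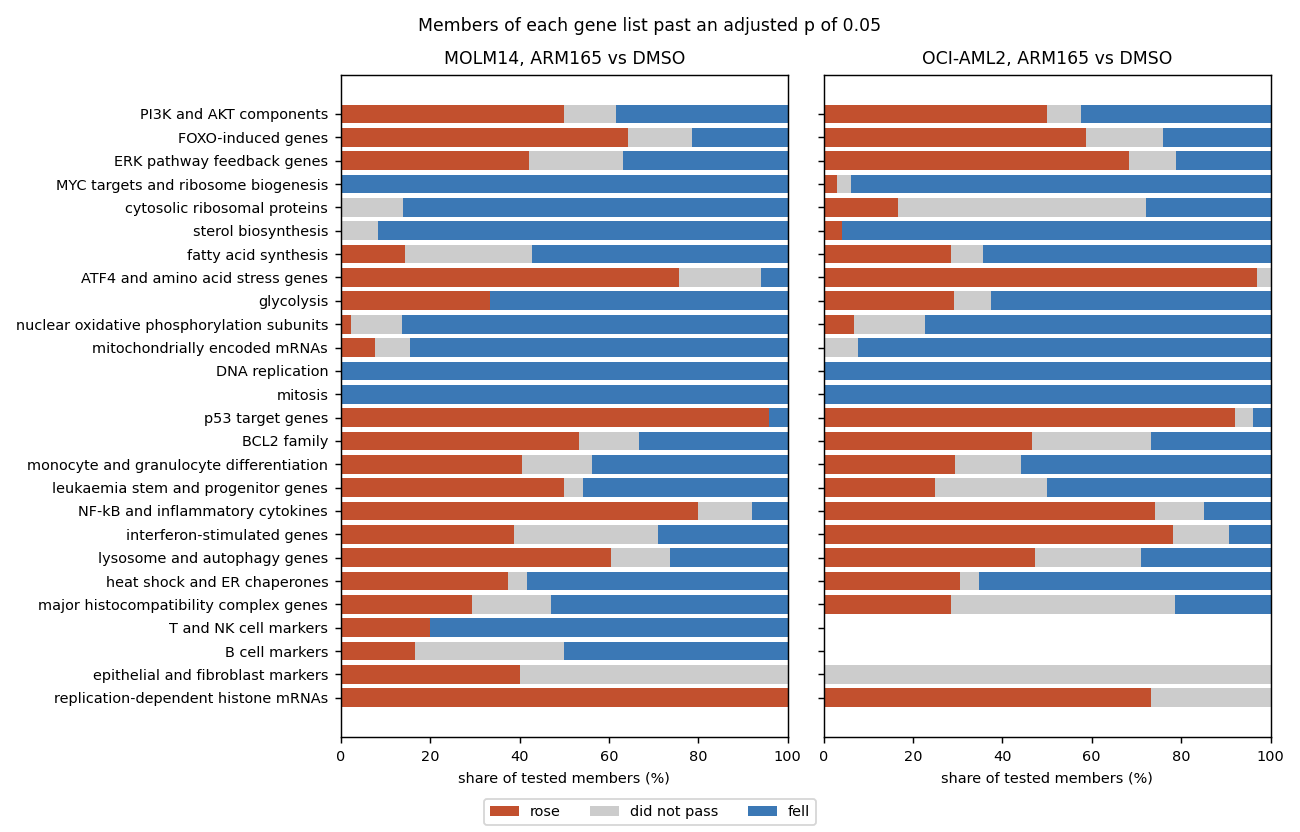
Share of the measured members of each gene list (horizontal axis, percent) that rose, did not pass or fell with ARM165 against DMSO by limma, for MOLM14 and OCI-AML2; lists without a bar were not tested in that line. In MOLM14, 40 of 40 DNA replication genes and 34 of 34 mitosis genes fell, and in OCI-AML2 40 of 40 and 34 of 34, and with quantile normalization the sign of the list test for ribosomal proteins reversed in MOLM14.

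The same comparison was made in OCI-AML2. There PIK3CG fell with ARM165 from 3084 ± 199 to 1239 ± 39.3 (change -1.31 ± 0.057, adjusted p = 1.90e-11). PIK3R5 rose from 1526 ± 133 to 3472 ± 63.2 (change 1.19 ± 0.070, adjusted p = 5.19e-10). AKT1 fell from 9146 ± 685 to 6572 ± 347 and AKT2 from 1869 ± 195 to 1161 ± 106 (changes -0.47 ± 0.061 and -0.69 ± 0.081, adjusted p = 4.41e-06 and 1.78e-06), each below the DMSO mean in 4 of 4 libraries. PIK3R6 had a change of -0.76 ± 0.32 that only just passed (adjusted p = 0.0493). It was lost without the filter on low values (adjusted p = 0.105) and in 8 of 12 fits that left out 1 library (adjusted p from 0.0131 to 0.161). In the PI3K and AKT list, 13 of 26 measured members rose, 11 fell and 2 did not pass (adjusted p = 0.899).

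Of 15377 genes, 10125 (65.8%) changed with ARM165 in OCI-AML2 by limma, 5263 higher and 4862 lower, and 2298 and 2066 of these had a log2 change of at least 1 in size. The median size of the log2 change over all genes tested was 0.66. That is larger than the change of AKT1, near that of AKT2 and smaller than those of PIK3CG and PIK3R5. CLDN1, a tight junction gene, rose from 9.25 ± 7.34 to 16449 ± 1475 (change 11.12 ± 0.55). XIRP1 was listed at 9.46, 0, 0 and 0 with DMSO and at 568, 582, 818 and 609 with ARM165. Among the largest falls were GP1BB (-5.44 ± 1.35), SIRPD (-4.16 ± 0.85) and TCTEX1D1 (-4.02 ± 0.37). GP1BB, a platelet glycoprotein gene that overlaps a read-through transcript, spread widely with ARM165 (75.4 ± 117 against 474 ± 65.4 with DMSO).

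Most members of the DNA replication, mitosis, MYC target and sterol lists fell in OCI-AML2, and these list calls held with an estimated correlation. For DNA replication, 40 of 40 measured members fell (median -1.77, adjusted p = 2.33e-20, adjusted p = 0.0149 with an estimated correlation). Examples were UHRF1 (-2.37 ± 0.045) and MCM3 (-1.85 ± 0.044). For mitosis, 34 of 34 measured members fell (median -1.38, adjusted p = 1.44e-15, adjusted p = 0.0313 with an estimated correlation). Examples were TPX2 (-1.42 ± 0.051) and AURKB (-1.92 ± 0.070). For MYC targets and ribosome biogenesis, 31 of 33 measured members fell, 1 rose and 1 did not pass (median -1.10, adjusted p = 2.30e-12, adjusted p = 0.0313 with an estimated correlation). Examples were NOP56 (-1.48 ± 0.053) and NOLC1 (-1.36 ± 0.051). For sterol biosynthesis, 23 of 24 measured members fell, 1 rose and 0 did not pass (median -0.95, adjusted p = 1.90e-08, adjusted p = 0.0272 with an estimated correlation). TMEM97, a member, fell by 2.41 (SE 0.069) on the log2 scale.

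Most members of the ATF4, p53 target, NF-kB and histone lists rose, with list calls that also held. In the ATF4 list, 31 of 32 measured members rose, 0 fell and 1 did not pass (median 1.60, adjusted p = 2.53e-13, adjusted p = 0.00724 with an estimated correlation). Examples were DDIT3 (4.56 ± 0.065) and ATF5 (3.26 ± 0.052). In the p53 target list, 23 of 25 measured members rose, 1 fell and 1 did not pass (median 1.51, adjusted p = 2.82e-07, adjusted p = 0.0313 with an estimated correlation). CDKN1A rose by 5.52 (SE 0.092) and TNFRSF10B, a death receptor gene, rose by 2.76 (SE 0.073). In the NF-kB and cytokine list, 20 of 27 measured members rose, 4 fell and 3 did not pass (median 1.45, adjusted p = 0.000498, adjusted p = 0.0313 with an estimated correlation). Examples were TRAF1 (4.17 ± 0.094) and IRF1 (3.59 ± 0.080). Among the histone genes, 11 of 15 measured members rose, 0 fell and 4 did not pass (median 2.38, adjusted p = 0.000961, adjusted p = 0.0272 with an estimated correlation). Examples were HIST1H2AC (4.84 ± 0.12) and HIST1H1C (4.03 ± 0.12).

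A further 7 lists were called in OCI-AML2 with the preset correlation and lost with an estimated one. Interferon-stimulated genes mostly rose (25 of 32 measured members rose, 3 fell and 4 did not pass, median 1.34, adjusted p = 0.000131, adjusted p = 0.213 with an estimated correlation). Members included IFIT2 (3.00 ± 0.20) and STAT2 (1.54 ± 0.097). In the FOXO list, 17 of 29 measured members rose, 7 fell and 5 did not pass (adjusted p = 0.0260, adjusted p = 0.219 with an estimated correlation). Members included TXNIP (2.51 ± 0.063) and FOXO3 (1.59 ± 0.059). In ERK feedback, 13 of 19 measured members rose, 4 fell and 2 did not pass (median 1.02, adjusted p = 0.0115, adjusted p = 0.150 with an estimated correlation). Members included PHLDA1 (6.92 ± 0.13) and DUSP5 (3.25 ± 0.081). In nuclear oxidative phosphorylation, 34 of 44 measured members fell, 3 rose and 7 did not pass (adjusted p = 1.79e-06, adjusted p = 0.346 with an estimated correlation). Members included ATP5MC1 (-1.58 ± 0.087) and ATP5F1A (-1.08 ± 0.059). Of the mitochondrially encoded mRNAs, 12 of 13 measured members fell, 0 rose and 1 did not pass (adjusted p = 0.000187, adjusted p = 0.273 with an estimated correlation). Members included MT-ND5 (-0.81 ± 0.060) and MT-ND3 (-0.75 ± 0.071). In monocyte and granulocyte differentiation, 19 of 34 measured members fell, 10 rose and 5 did not pass (median -0.66, adjusted p = 0.00367, adjusted p = 0.108 with an estimated correlation). Members included IRF8 (-2.11 ± 0.061) and CCR2 (-2.75 ± 0.080). Among chaperones, 15 of 23 measured members fell, 7 rose and 1 did not pass (median -1.07, adjusted p = 0.00367, adjusted p = 0.273 with an estimated correlation). Members included CALR (-2.27 ± 0.051) and PDIA4 (-1.52 ± 0.047), both genes of the endoplasmic reticulum.

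The remaining lists in OCI-AML2 were not called. For leukaemia stem and progenitor genes, 12 of 24 measured members fell, 6 rose and 6 did not pass (adjusted p = 0.0928). Members included MYB (-2.40 ± 0.055) and CTSG (-2.81 ± 0.067). For fatty acid synthesis, 9 of 14 measured members fell, 4 rose and 1 did not pass (adjusted p = 0.0510). Members included FADS2 (-1.56 ± 0.080) and ME1 (2.42 ± 0.087). For glycolysis, 15 of 24 measured members fell, 7 rose and 2 did not pass (adjusted p = 0.0646). Members included LDHA (-1.67 ± 0.054) and VEGFA (3.10 ± 0.067). Of the ribosomal proteins, 10 of 36 measured members fell, 6 rose and 20 did not pass (adjusted p = 0.480). Members included EEF1A1 (-1.33 ± 0.070) and RPS16 (-0.56 ± 0.072). In the BCL2 family, 7 of 15 measured members rose, 4 fell and 4 did not pass (adjusted p = 0.304). Members included BCL2 (-1.57 ± 0.052) and BMF (2.57 ± 0.099). In lysosome and autophagy, 18 of 38 measured members rose, 11 fell and 9 did not pass (adjusted p = 0.224). Members included SQSTM1 (3.39 ± 0.057) and MAP1LC3B (2.91 ± 0.060). In the major histocompatibility complex list, 4 of 14 measured members rose, 3 fell and 7 did not pass (median 0.056, mean -0.078, adjusted p = 0.899). Members included CD74 (-1.44 ± 0.066) and NLRC5 (-1.48 ± 0.069). Of 5 epithelial and fibroblast markers 0 passed (adjusted p = 0.445). The T and NK, B, and erythroid and megakaryocyte lists had 4, 4 and 2 measured members, too few to test. Among them NKG7 (-0.52 ± 0.12) and ITGA2B (-2.73 ± 0.52) fell, and FCRLA was at 2.53, 3.82, 0 and 6.06 with DMSO and 54.9, 57.3, 32.98 and 32.5 with ARM165. Counts adjusted over the list alone differed from those over all genes for the ribosomal proteins (5 higher, 9 lower), the monocyte list (20 lower), the NF-kB list (21 higher) and interferon-stimulated genes (26 higher).

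Whether ARM165 acted differently in the lines was tested in a fit of all 24 libraries. The fall of PIK3CG was larger in OCI-AML2 (difference -0.79 ± 0.088, adjusted p = 1.08e-07), and the rise of PIK3R5 smaller (difference -0.62 ± 0.11, adjusted p = 0.000105). The differences were 0.59 ± 0.089 for AKT1 and 0.29 ± 0.093 for AKT2 (adjusted p = 8.44e-06 and 0.0130). The AKT2 call was lost with quantile normalization (adjusted p = 0.0791). For PIK3R6, which did not pass, the interval was -0.88 to 0.64. Across 14287 genes the changes in the lines correlated with Pearson's r of 0.717 and Spearman's rho of 0.711. Genes are not independent replicates. Of 7971 genes called in both lines, 3824 were higher in both and 3511 lower in both, against 1837 and 1619 for independent lists, and 636 went in opposite directions.

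By limma, 6053 genes had a different change in the lines, 3471 with a change more positive in OCI-AML2 and 2582 with one more negative. CPXM1 rose in OCI-AML2, from a mean of 14.4 to 326, and fell in MOLM14, from 701 to 259 (difference 5.94 ± 0.63). PHLDA2 likewise rose in OCI-AML2, from 47.3 to 756, and fell in MOLM14, from 743 to 485 (difference 5.04 ± 0.62). TMTC1 rose in MOLM14, from 4.39 to 351, and had means of 792 and 775 in OCI-AML2 (difference -6.30 ± 0.74). BMP6, a bone morphogenetic protein gene, rose in MOLM14 from 0.928 to 63.5 with means of 5.54 and 4.11 in OCI-AML2 (difference -6.46 ± 1.41). CLDN1 was listed at 0 in MOLM14 with DMSO, so its difference (5.35 ± 0.70) has no fixed size. FSCN2 had means of 2.59 and 20.1 in MOLM14 and 36.1 and 7.05 in OCI-AML2, with DMSO and ARM165 (difference -5.41 ± 1.10).

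Of 23 lists, 12 were called between the lines with the preset correlation and 0 with an estimated one. In the ATF4 list 20 of 32 members were higher, 2 lower and 10 did not pass (median 0.59, adjusted p = 2.15e-07, adjusted p = 0.110 with an estimated correlation). In ERK feedback 11 of 19 members were higher, 1 lower and 7 did not pass (median 0.82, adjusted p = 0.000580, adjusted p = 0.110 with an estimated correlation). Among interferon-stimulated genes 16 of 30 members were higher, 3 lower and 11 did not pass (median 0.75, adjusted p = 0.00306, adjusted p = 0.394 with an estimated correlation). In the DNA replication list the fall was larger in OCI-AML2, with 24 of 40 members lower, 1 higher and 15 that did not pass (median -0.36, adjusted p = 4.08e-07, adjusted p = 0.256 with an estimated correlation). The other differences ran from -0.37 for leukaemia stem and progenitor genes (adjusted p = 0.00220, adjusted p = 0.110 with an estimated correlation) upward. The highest was 0.48 for fatty acid synthesis (adjusted p = 0.0128, adjusted p = 0.110 with an estimated correlation). Others were MYC targets at 0.29 (adjusted p = 0.000250, adjusted p = 0.396 with an estimated correlation) and lysosome and autophagy at -0.21 (adjusted p = 0.00306, adjusted p = 0.383 with an estimated correlation). Mitosis was at -0.12 (adjusted p = 0.0295, adjusted p = 0.634 with an estimated correlation) and mitochondrially encoded mRNAs at -0.20 (adjusted p = 0.0295, adjusted p = 0.634 with an estimated correlation). The call for the ribosomal proteins (median 0.26, adjusted p = 8.12e-05, adjusted p = 0.634 with an estimated correlation) was lost with quantile normalization (adjusted p = 0.546). So was that for glycolysis (median 0.27, adjusted p = 0.0150, adjusted p = 0.569 with an estimated correlation), at adjusted p = 0.137. The other 11 lists had adjusted p from 0.124 to 0.8287, with 4 of them differing in sign between median, mean and test. Adjusted over the list alone, 21 ATF4 members, 24 ribosomal proteins and 21 MYC targets were higher and 27 DNA replication genes lower.

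The compounds were compared directly at their unstated doses. In MOLM14, 10712 of 15288 genes differed between ARM165 and AZ2 by limma, 5516 higher with ARM165 and 5196 lower. The differences were -0.42 ± 0.067 for PIK3CG, 1.83 ± 0.096 for PIK3R5, -1.06 ± 0.063 for AKT1 and -1.02 ± 0.048 for AKT2 (adjusted p up to 4.12e-05). PIK3R6 did not pass (interval -0.64 to 0.050, adjusted p = 0.116, but 0.00556 with quantile normalization and 0.0380 without AZ2 replicate 4). DUSP8, a phosphatase gene of the MAP kinase pathways, was at 0, 1.85e-07, 12.7 and 0 with AZ2 and 4013, 3851, 3801 and 3164 with ARM165. SPRR2D was again listed at 0 in every AZ2 library. The chemokine gene CCL23 fell from 50.03 ± 22.5 to 2.00 ± 2.31 and APLN from 111 ± 8.84 to 5.75 ± 3.01. Of 26 lists, 15 were called, 6 higher and 9 lower with ARM165, none with an estimated correlation (adjusted p from 0.0661 to 0.460). They included DNA replication with 40 of 40 members lower (median -1.42, adjusted p = 3.55e-17, adjusted p = 0.106 with an estimated correlation) and p53 targets with 23 of 24 higher (median 1.64, adjusted p = 1.15e-09, adjusted p = 0.106 with an estimated correlation). For the ribosomal proteins, with 33 of 36 members lower, the sign of the list test reversed with quantile normalization (adjusted p = 0.797).

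In OCI-AML2, 10124 of 15377 genes differed between ARM165 and AZ2 by limma, 5300 higher and 4824 lower. The differences were -1.30 ± 0.057 for PIK3CG, 1.10 ± 0.070 for PIK3R5, -0.52 ± 0.061 for AKT1 and -0.67 ± 0.081 for AKT2 (adjusted p up to 2.28e-06). PIK3R6 did not pass, with an interval of -1.07 to 0.31. CLDN1 was at 6.90 ± 2.53 with AZ2 and 16449 ± 1475 with ARM165. ABLIM3, an actin-binding protein gene, was at 0, 1.58, 0 and 6.81 with AZ2 and 568, 442, 584 and 507 with ARM165. HK3, a hexokinase gene, fell by 4.15 (SE 0.25) and HAL, the histidine ammonia-lyase gene, fell by 3.74 (SE 0.20) on the log2 scale. Of 24 lists, 15 were called and 7 held with an estimated correlation: DNA replication (0.0145), mitosis, MYC targets, p53 targets, NF-kB and histones (each adjusted p = 0.0346) and ATF4 (0.00695). Sterol biosynthesis, with 16 of 24 members lower and 2 higher, had a median of -0.48 (adjusted p = 0.000193, adjusted p = 0.0864 with an estimated correlation).

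Between the lines, 6252 genes differed in their ARM165 to AZ2 change by limma, and 12 of 23 lists were called, none with an estimated correlation (adjusted p from 0.105 to 0.679). PIK3CG differed by -0.88 ± 0.088, PIK3R5 by -0.74 ± 0.11, AKT1 by 0.54 ± 0.089 and AKT2 by 0.35 ± 0.093 (adjusted p up to 0.00393). PIK3R6 did not pass (interval -0.85 to 0.68). The fall of sterol genes with ARM165 against AZ2 was smaller in OCI-AML2 than in MOLM14 (in the difference, 14 of 24 members were higher, 1 lower and 9 did not pass, 16 higher when adjusted over the list alone, median 0.26, adjusted p = 0.000682, adjusted p = 0.236 with an estimated correlation). Against DMSO, the ARM165 change of this list was not called different between the lines by camera (median difference -0.0057, mean 0.14, adjusted p = 0.807). The AZ2 change against DMSO was more negative in OCI-AML2 (median difference -0.35), and the comparison with AZ2 includes that fall.

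Finally, the AZ2 and ARM165 changes, which share their DMSO libraries, were set against each other. Across genes, Pearson's r was 0.110 in MOLM14 and 0.199 in OCI-AML2, and Spearman's rho was -0.00108 and 0.166. In MOLM14, r was 0.210 with no filter and 0.0435 with a minimum value of 50. Unchanged groups simulated against the same controls gave r of 0.503 and 0.4996. These are no reference for the real r, because the simulation held no ARM165 effect. Real ARM165 changes that are unrelated to those of AZ2 widen the spread and lower r. The covariance was 0.0482 in MOLM14 (simulated 0.0550) and 0.0962 in OCI-AML2 (simulated 0.0672), or 0.0633 and 0.0810 when the simulation used the spread of the DMSO libraries themselves. The covariance in OCI-AML2 exceeded the highest simulated value in both forms (0.0743 and 0.0899), and that in MOLM14 lay below both simulated means. With no ARM165 effect in the simulations, their range is no test of a shared response. With different DMSO libraries for each compound, r averaged -0.0282 and 0.0252 over 6 splits. In OCI-AML2, 13 of the 16 genes lower with AZ2 were also lower with ARM165 (5.06 for independent lists). With split controls, 5 to 13 genes were lower with AZ2 and 3 to 11 with both. EGR1 was higher with both (0.342 for independent lists). C6orf223 and CECR2, lower with AZ2, were higher with ARM165, with changes of 1.94 and 1.74 (adjusted p = 2.86e-07 and 3.43e-07). Part of these overlaps may come from the shared controls.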

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

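Of 402 groups of 4 libraries for the genes named by the rule within a line, 31 (7.71%) had a library far from the other 3 on a gap test, where about 1 in 20 would by chance, and none of these libraries was left out. The value given for each is the gap to the nearest other library as a share of the range. In MOLM14 with DMSO these were HEY1 in replicate 2 (1), NOLC1 in replicate 3 (0.838), NDUFS7 in replicate 4 (0.899), MT-ND5 in replicate 3 (0.874), IRF8 in replicate 3 (0.830), BST2 in replicate 2 (0.911) and TAP2 in replicate 1 (0.959). In MOLM14 with AZ2 they were AKT1 in replicate 4 (0.976), FDPS in replicate 2 (0.850), MT-ND6 in replicate 2 (0.847), CDKN1A in replicate 3 (0.974), SQSTM1 in replicate 3 (0.875) and DUSP8 in replicate 3 (1). MOLM14 with ARM165 had CDKN1A in replicate 4 (0.908), IRF1 in replicate 4 (0.832), PSAP in replicate 4 (0.836), SQSTM1 in replicate 4 (0.861), HIST1H2AC in replicate 4 (0.948) and HIST1H1C in replicate 4 (0.860), and replicate 4 of that group recurs in 6 genes. For OCI-AML2 with DMSO the list was PIK3R5 in replicate 2 (0.945), XIRP1 in replicate 1 (1), MT-ND3 in replicate 1 (0.842), UHRF1 in replicate 3 (0.846), IRF1 in replicate 1 (0.830) and HIST1H2AC in replicate 4 (0.870). For OCI-AML2 with AZ2 it was EEF1A1 in replicate 4 (0.866), MT-ND5 in replicate 3 (0.856), IRF8 in replicate 3 (0.863) and FCRLA in replicate 1 (1), and for OCI-AML2 with ARM165 it was PIK3CG in replicate 1 (0.959) and XIRP1 in replicate 3 (0.837).

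The other results here are differences between the lines that passed the test of the difference itself, given as log2 values of OCI-AML2 minus MOLM14. For AZ2 against DMSO the genes were -0.50 for FDFT1, -0.66 for HMGCS1, -0.53 for IDI1 and -0.49 for INSIG1. The list medians were 0.040 for ERK pathway feedback genes, -0.063 for MYC targets and ribosome biogenesis, -0.055 for cytosolic ribosomal proteins, -0.35 for sterol biosynthesis, -0.081 for fatty acid synthesis, -0.093 for glycolysis, -0.10 for nuclear oxidative phosphorylation subunits, -0.071 for DNA replication, 0.033 for p53 target genes, 0.050 for NF-kB and inflammatory cytokines and -0.095 for heat shock and ER chaperones.

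For ARM165 against DMSO, the genes were 0.59 for AKT1, 0.29 for AKT2, -0.79 for PIK3CG, -0.62 for PIK3R5, 1.28 for ANXA8, 0.89 for ATF5, -0.40 for ATP5F1A, -0.35 for AURKB, -0.84 for BCL2, -1.23 for BMF, -6.46 for BMP6, 0.75 for BST2, -0.72 for CALR, 0.45 for CCR2, 2.82 for CDKN1A, 5.35 for CLDN1, 5.94 for CPXM1, -1.17 for CTSG, 0.65 for DDIT3 and 2.27 for DUSP5. Further genes were 1.86 for FADS2, -0.46 for FLT3, -5.41 for FSCN2, -0.72 for HIST1H1C, 1.12 for HSPA8, 0.48 for HSPH1, -0.60 for IL1B, 1.70 for IRF1, -0.63 for IRF8, -2.29 for KLHDC7B, 1.66 for LYZ, -0.36 for MCM3, 0.65 for ME1, -0.34 for MT-ND3, -1.20 for MYB, -1.03 for NLRC5, -0.998 for PDIA4 and 1.80 for PHLDA1. The rest were 5.04 for PHLDA2, -0.21 for PSAP, 0.93 for RPL3, 2.25 for S100A8, 1.37 for SCD, 1.64 for SESN2, -5.40 for SPRR2D, 1.12 for SQSTM1, -4.63 for TCTEX1D1, -6.30 for TMTC1, 1.24 for TNFRSF10B, 0.32 for TXNIP, -0.24 for UHRF1, 0.87 for VEGFA and 3.45 for XIRP1. The list medians were 0.82 for ERK pathway feedback genes, 0.29 for MYC targets and ribosome biogenesis, 0.26 for cytosolic ribosomal proteins, 0.48 for fatty acid synthesis, 0.59 for ATF4 and amino acid stress genes, 0.27 for glycolysis, -0.20 for mitochondrially encoded mRNAs, -0.36 for DNA replication, -0.12 for mitosis, -0.37 for leukaemia stem and progenitor genes, 0.75 for interferon-stimulated genes and -0.21 for lysosome and autophagy genes.

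For ARM165 against AZ2 the genes were 0.54 for AKT1, 0.35 for AKT2, 5.67 for CLDN1, -4.13 for DUSP8, -2.81 for HK3, -0.88 for PIK3CG, -0.74 for PIK3R5 and -6.31 for SPRR2D. The list medians were 0.75 for ERK pathway feedback genes, 0.35 for MYC targets and ribosome biogenesis, 0.34 for cytosolic ribosomal proteins, 0.26 for sterol biosynthesis, 0.42 for fatty acid synthesis, 0.64 for ATF4 and amino acid stress genes, 0.40 for glycolysis, 0.18 for nuclear oxidative phosphorylation subunits, -0.30 for DNA replication, -0.30 for leukaemia stem and progenitor genes, 0.75 for interferon-stimulated genes and -0.14 for lysosome and autophagy genes. SPRR2D, KLHDC7B, XIRP1, DUSP8, CLDN1, BMP6, FSCN2, TMTC1 and HK3 had a mean under 10 in a group of at least 1 line, so their differences depend on the 1 added to each value and are no bound on the true difference. Every list call between the lines was lost with an estimated correlation except that for sterol biosynthesis with AZ2.

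The first pattern weighed was that ARM165 changed many genes in both lines and AZ2 few or none, and of its tests only that for exchanged libraries was chosen after results were seen. A difference in library depth was tested by thinning all libraries to the same depth, and the line with fewer calls still had 10123 (10722 in MOLM14). A few genes taking many of the counts was tested by rescaling without the 50 most abundant genes, which left 10182 (10764 in MOLM14). An ARM165 library exchanged with a DMSO or AZ2 library was found for 0 of 24 libraries. None of these 3 accounts for the many genes called with ARM165. After the same thinning and rescaling, AZ2 against DMSO had 0 and 0 calls in MOLM14 and 18 and 14 in OCI-AML2. Thinning only removes reads, so calls that AZ2 might gain at a greater depth were not tested. An exchange between DMSO and AZ2 libraries was not tested, and a difference between the compounds or their unstated doses stays open.

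The second pattern was that sterol genes fell with AZ2 more in OCI-AML2 than in MOLM14, with the tests of the change in OCI-AML2 chosen before results were seen and those of the difference between lines after. Without any 1 DMSO or AZ2 library of OCI-AML2 the median change of the sterol list in OCI-AML2 lay between -0.47 and -0.42, and with another scaling between libraries the median nearest 0 was -0.42. Without any 1 DMSO or AZ2 library of either line the median difference between lines lay between -0.37 and -0.32, and with another scaling the one nearest 0 was -0.32. Neither a single library nor the scaling accounts for this difference of medians, though the count of 4 genes called between lines fell to 0 without any of 7 single libraries. A difference between the lines in their response to AZ2 stays open.

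The third pattern was the rise of replication-dependent histone mRNAs with ARM165, with its test chosen before results were seen. Carry-over of RNA without a poly(A) tail was to be tested on other such RNAs, but the tables hold 0 of them with a value, so the test is void and the explanations cannot be told apart. No other explanation was tested.

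Whether chance can be excluded was asked by splitting the 8 libraries of a comparison into 4 and 4 in all 35 ways and counting the splits with at least as many calls, the real one included. For genes this was 35 for AZ2 against DMSO in MOLM14 (0 calls, highest other 2), 1 for ARM165 against DMSO (10623, highest other 1) and 1 for ARM165 against AZ2 (10712, highest other 1). In OCI-AML2 it was 1 for AZ2 against DMSO (17, highest other 2), 1 for ARM165 against DMSO (10125, highest other 0) and 1 for ARM165 against AZ2 (10124, highest other 1). For all but AZ2 against DMSO in MOLM14, the real groups gave more called genes than any other split. This is the smallest share that 35 splits can give. It is not adjusted over the comparisons and takes the libraries as independent, which the labels do not state. A split that mixes the groups also puts the treatment into the spread, so its low count is not a level under chance alone. For gene lists it was 4 for AZ2 in MOLM14 (6 lists, highest other 9), 2 for ARM165 against DMSO (15, highest other 15) and 1 for ARM165 against AZ2 (15, highest other 14). In OCI-AML2 the lists gave 5 for AZ2 (6, highest other 12), 2 for ARM165 against DMSO (15, highest other 15) and 2 for ARM165 against AZ2 (15, highest other 15). Other splits called as many lists in every comparison but ARM165 against AZ2 in MOLM14, where the highest other was 14 against 15. A split that mixes the groups unevenly keeps part of the treatment difference, so these counts do not settle whether chance explains them. The number of lists called with the preset correlation should not be read as evidence by itself.

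Between the lines, 100 splits were drawn. For genes, 4 reached the real count for AZ2 against DMSO (4 calls, highest other 11), 2 for ARM165 against DMSO (6053, highest other 6120) and 1 for ARM165 against AZ2 (6252, highest other 5690). For lists, 2 did for AZ2 against DMSO (11, highest other 12), 46 for ARM165 against DMSO (12, highest other 15) and 53 for ARM165 against AZ2 (12, highest other 16). These splits do not settle whether chance explains any of these counts, and they do not exclude it for the lists with ARM165. A split that mixes the groups in both lines takes out the treatment, in whole or in part, as well as its difference between lines. What it leaves of the treatment can differ between the lines. The high other splits keep the real groups of 1 line (8, 7 and 9 of 99 splits), while those that mix both lines reached at most 3, 1 and 2 genes. For AZ2, the split that called 11 genes against 4 for the real groups also kept the real groups of 1 line, and what it reflects was not tested.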

How the results depend on the processing

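Named genes and lists that were called kept their direction under every alternative in which they were tested, except in the list test of the ribosomal proteins under quantile normalization. That alternative gives EEF1A1 in MOLM14 the same value in every library, so it is no test of it. CYP51A1, IDI1, FDPS, AC025048.6 and FTL, named outside the rule, and genes named in a further comparison were run after results were seen. The cause was not tested for any result that changed. Genes under the filter were tested only in the alternative without it. With every library thinned to the lowest total, 0 genes were called for AZ2 against DMSO in MOLM14 and 18 in OCI-AML2, and what depth limits for single genes was not compared. The planned count models were not run because whole counts could not be recovered. With log2(value + 5), OCI-AML2 AZ2 against DMSO had 2 genes higher, and the correlation between lines of ARM165 changes was 0.746. With no filter, it had 5 higher and 10 lower, the AZ2 difference between lines had 2 higher, the correlation of AZ2 and ARM165 changes in MOLM14 was 0.210, and that between lines of ARM165 changes was 0.555. With a minimum value of 50 these correlations were 0.0435 and 0.798. It also lost the list calls between lines for AZ2 of ERK feedback (0.0605), MYC targets and ribosomal proteins (each adjusted p = 0.0587) and that of oxidative phosphorylation for ARM165 against AZ2 (0.0890), and added fatty acid synthesis for AZ2 in MOLM14 (0.0408). With quantile normalization, OCI-AML2 AZ2 had 2 genes higher, 2 lists were called between lines for AZ2, and the test of ribosomal proteins reversed in MOLM14 for ARM165 against DMSO (adjusted p = 0.692), against AZ2 (0.797) and between lines for AZ2 (0.566). With only the groups compared, MOLM14 AZ2 had 1 gene, 1 lower, OCI-AML2 AZ2 had 2 higher, and the AZ2 difference between lines had 8 genes, 2 higher. Quantile normalization also lost the calls of mitochondrially encoded mRNAs for ARM165 against AZ2 in MOLM14 (adjusted p = 0.266) and, between lines for that comparison, of ribosomal proteins (0.485) and oxidative phosphorylation (0.190). It added mitochondrially encoded mRNAs (0.00203) and mitosis (0.00343) there, and chaperones between lines for ARM165 against DMSO (0.0379). Robust empirical Bayes and library weights each gave 2 genes higher for OCI-AML2 AZ2.

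The labels do not say whether replicate numbers pair the libraries. Libraries of the same number in different groups had correlations of their deviations from -0.0373 to 0.0558 over 24 pairs (mean 0.0135). Those of different numbers had -0.0633 to 0.0463 over 72 pairs (mean -0.0045). These values show no strong pairing and do not exclude a weak one. With the replicate block, OCI-AML2 AZ2 against DMSO had 10 genes, 9 lower, and the AZ2 difference between lines had 2 genes, 2 lower. The replicate block lost the calls of C6orf223, CECR2, MVK and FADS1 with AZ2 in OCI-AML2 (adjusted p = 0.0843, 0.0904, 0.101 and 0.143), and of CYP51A1, FDPS and AC025048.6 (0.101, 0.0577 and 0.0653). It also lost those of IDI1 and INSIG1 between lines (each adjusted p = 0.0643), added that of fatty acid synthesis with AZ2 in MOLM14 (0.0485), and changed no other call.

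With an estimated correlation, the lists called for AZ2 against DMSO, ARM165 against DMSO and ARM165 against AZ2 were 0, 0 and 0 in MOLM14, 2, 8 and 7 in OCI-AML2, and 1, 0 and 0 between lines. With fry, which does not compare a list with other genes, lists were tested for a shift in a common direction, so its counts are not comparable. They were 0, 23 and 25 in MOLM14, 2, 23 and 22 in OCI-AML2, and 1, 16 and 16 between lines. Its test of change in either direction called 3, 26 and 26 lists in MOLM14, 4, 23 and 23 in OCI-AML2, and 1, 23 and 23 between lines.

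With each library left out, MOLM14 AZ2 had 0 to 3 genes, all lower (0 to 3): 3 without AZ2 replicate 3 and 1 without DMSO replicate 4, AZ2 replicate 1 or ARM165 replicate 4. OCI-AML2 AZ2 had 9 to 17 genes, 8 to 16 lower and 1 to 2 higher: 9 without DMSO replicate 1 or AZ2 replicate 2, 10 without DMSO replicate 4 or AZ2 replicate 3, 11 without AZ2 replicate 1, and 2 higher without DMSO replicate 2 or ARM165 replicate 4. The overlap of AZ2 and ARM165 calls in OCI-AML2 was 9 to 14, with 9 without DMSO replicate 1, AZ2 replicate 2 or AZ2 replicate 3. The AZ2 difference between lines had 0 to 7 genes, 0 to 7 lower and 0 to 1 higher. It had 0 without MOLM14 DMSO replicate 1, 2 or 4, MOLM14 AZ2 replicate 3, OCI-AML2 DMSO replicate 1 or OCI-AML2 AZ2 replicate 1 or 3. It had 1 without OCI-AML2 DMSO replicate 4 or ARM165 replicate 1 or 3, 2 without MOLM14 AZ2 replicate 1 or 4 or OCI-AML2 DMSO replicate 2, and 7 without MOLM14 DMSO replicate 3. It had 1 higher without MOLM14 AZ2 replicate 1, MOLM14 ARM165 replicate 3, OCI-AML2 AZ2 replicate 2 or 4, or OCI-AML2 ARM165 replicate 2. Its lists numbered 2 to 12: 2 without MOLM14 AZ2 replicate 3, 5 without MOLM14 DMSO replicate 2, and 7 without MOLM14 AZ2 replicate 1, OCI-AML2 DMSO replicate 3 or OCI-AML2 AZ2 replicate 1.

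Over all alternatives, adjusted p of named genes that lost a call ranged from 0.00185 to 0.164 for C6orf223, 0.0134 to 0.215 for CECR2, 0.0284 to 0.202 for FADS1, 0.0131 to 0.146 for MVK, 0.0168 to 0.127 for CYP51A1, 0.0353 to 0.157 for FDPS and 0.0103 to 0.140 for AC025048.6 with AZ2 in OCI-AML2. Between lines with AZ2 it ranged to 0.186 for FDFT1, 0.0772 for HMGCS1, 0.154 for IDI1 and 0.154 for INSIG1. For PIK3R6 with ARM165 in OCI-AML2 it was 0.0131 to 0.161, and for AKT2 between lines 0.00189 to 0.0791.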

Other observations

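FTL, which encodes ferritin light chain, took a larger share of all values with ARM165 than with DMSO in both lines, from 0.1799% to 0.623% in MOLM14 and from 0.498% to 2.67% in OCI-AML2. The log2 changes by limma were 1.60 (SE 0.056, adjusted p = 1.71e-12) in MOLM14 and 2.39 (SE 0.072, adjusted p = 3.25e-13) in OCI-AML2. With AZ2 they were 0.049 and -0.014, and neither passed. FTL was looked at after its values were seen, and it has many processed pseudogenes, so its share is uncertain. EEF1A1 took 4.598% of all values with DMSO and 1.78% with ARM165 in MOLM14, and 2.51% and 1.02% in OCI-AML2, and mitochondrially encoded genes took 5.29% and 4.80%, and 7.61% and 5.41%.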
